A study of Mus musculus with 8 samples.

How the data were processed

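RNA from 8 pools of mouse rib chondrocytes, 4 labelled control and 4 labelled transgenic, was hybridised to one-colour biotin-labelled Affymetrix arrays, 1 array per pool. Per the labels' protocols, rib cages of day 18.5 embryos were digested in 0.25% collagenase and 0.25% trypsin with EDTA and then in fresh collagenase, the cells were passed through a 70 micrometre strainer, and total RNA was extracted with Trizol. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version, the detection calls and the scanner settings are not given in the sources used here. The values themselves show the scaling: the mean of each array over all probe sets, without the top and bottom 2%, was 500. MAS5 subtracts signal of mismatch probes, which leaves dim probe sets noisy, so fold changes of dim genes carry wide errors.

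Signals were taken as deposited, 64 control probe sets of the manufacturer were left out, and the remaining 45037 were turned to log2(signal + 32), where 32 is the median over arrays of the 25th percentile of signal. The added constant makes the log2 fold changes of dim probe sets smaller than those of their signals. Probe sets entered the test where their mean over all 8 arrays lay above the median, which kept 22518. No further normalization between arrays was applied. Differences were tested with lmFit and eBayes with an intensity trend in limma 3.58.1 (statmod 1.5.0, R 4.3.3), with 1 coefficient for transgenic minus control and Benjamini-Hochberg adjustment over all tested probe sets. Single values were tested with exact two-sided permutation tests over all 70 assignments of the labels, which take no account of the litters. Errors are SDs of signals over 4 arrays or 95% intervals of the fitted log2 fold change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

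Probe sets were named through the platform annotation of GEO, with symbols looked up again by gene identifier in a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 of them. Of the probe sets considered, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here, 2269 of them among those tested. Genes were named from probe sets with 1 symbol, except the pair that both Hoxd4 and Hoxd3 are assigned to, which were the only ones for the overexpressed gene. No coordinates were given by the files, and none are printed.

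Before the data were examined, 38 gene lists with 843 members were fixed, for chondrocyte programmes, signaling pathways, Hox genes, other cell types that a rib digest could hold, dissociation stress, sex-linked and housekeeping genes. Of the members 784 were on the array and 605 were tested. Each list with at least 3 tested members was compared with all other genes by camera in limma with its preset correlation of 0.01, with 1 probe set per gene (the brightest tested), and Benjamini-Hochberg adjustment over 36 lists. The adjusted p values with a correlation estimated for each list were computed too, and with it none of the 4 called lists held. Members were counted at an adjusted p under 0.05 over all probe sets and adjusted over the list alone.

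The named genes followed a rule set at the same time: Hoxd4; the 12 genes with the largest rise and the 12 with the largest fall that ran the same way in all 4 litters, taken from probe sets past the adjusted threshold and, where fewer passed, filled from those with an unadjusted p under 0.01; and up to 4 members of each list with the smallest p. Since none passed, all 24 were filled in.

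The number in each sample's label is that of its litter, so same-numbered control and transgenic arrays are paired by litter. This was checked by correlating their deviations from the group means over the tested probe sets: the correlations were 0.28, 0.17, 0.04 and 0.15 for litters 1, 2, 3 and 4, with a mean of 0.16 against -0.05 for arrays of different litters, and in 3 of 4 litters the control array went best with its own. The labels give the litter but name no test or covariate, and the chosen fit had no block. It therefore ignores the pairing by litter, and the fit with the litter as a block was run beside it. The labels do not say how many embryos each pool held.

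The fits and list tests were tested on simulated data with known changes, 20 sets with 200 changed probe sets each among 22518. The simulated values took the SDs of the real fit as true, with independent probe sets and no litter effect. The rates therefore do not show which fit suits litters that differ. The fit without a block recovered 15.6%, 60.1%, 91.1% and 99.7% of changes of 1.25-fold, 1.5-fold, 2-fold and 3-fold, with 6.59% false calls among all calls, and the fit with it 12.6%, 57.7%, 90.5% and 99.7%. Camera found lists of 25 genes shifted by 0.15 on the log2 scale in 100% of the sets at an unadjusted p under 0.05 and unshifted lists in 0%, with genes simulated as independent. Alternatives were the litter as a fixed or random block, pseudocounts of 1 and 128, no filter or a filter at the 75th percentile, quantile normalization, median centring, no intensity trend, array weights, leaving out each array or each litter, an adjusted p of 0.1, leaving out probe sets that can bind several transcripts, and for the lists an estimated correlation, the rotation test fry and the mean of all probe sets of a gene. Leaving out both arrays of a litter without the block and using the log2 level of Xist as a covariate were added after seeing the data.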

Results

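Gene expression was measured in primary chondrocytes, the cells of growing cartilage, freed by enzymes from the rib cages of FVB mouse embryos late in gestation (E18.5). Embryos of 4 litters, named here by replicate number, were sorted by genotype, which gave 1 wild-type control pool and 1 Hoxd4-transgenic pool per litter, 8 pools and 8 one-colour arrays in all. Each array reported 45101 probe sets, of which 22518 were bright enough to be tested, and the tested probe sets named 11016 genes. The median signal per array lay between 100.5 and 115 on the MAS5 scale, and rank correlations between arrays lay between 0.932 and 0.942, with no 2 arrays alike in value. The number of arrays, 4 per group, set the precision: the 95% interval of a log2 fold change reached 0.27 to either side of the estimate for the median probe set. The comparison asks which transcripts differ in rib chondrocytes when Hoxd4, a homeobox transcription factor that helps pattern the neck vertebrae, is overexpressed.

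Only a pair of probe sets stood for the overexpressed gene. The platform annotation assigns both to Hoxd4 and to its neighbour Hoxd3 together, and both were too dim for the main test. Whether the transgene holds the sequence they target is not known here. The brighter of the pair had signals of 27.3, 42.6, 4.10 and 256 in the control arrays of litters 1, 2, 3 and 4, and of 94.1, 415, 172 and 13 in the transgenic arrays of the same litters. It was therefore brighter in the array labelled transgenic in 3 of 4 litters and dimmer in litter 4. Its log2 fold change was 0.87 (95% interval -0.61 to 2.36), with an exact permutation p of 0.40, the smallest possible being 0.0286. Without litter 1, 2, 3 or 4 the log2 fold change was 0.80, 0.30, 0.33 and 2.06. The dimmer of the pair stayed near background on every array, with means of 26.5 ± 17.0 (SD, n = 4) in controls and 20.6 ± 6.75 (SD, n = 4) in transgenics and a log2 fold change of -0.12 (exact permutation p = 0.66). Since the brighter probe set goes against the label in litter 4, the groups below are those the labels give, and each direction rests on those labels.

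**Figure D1:**
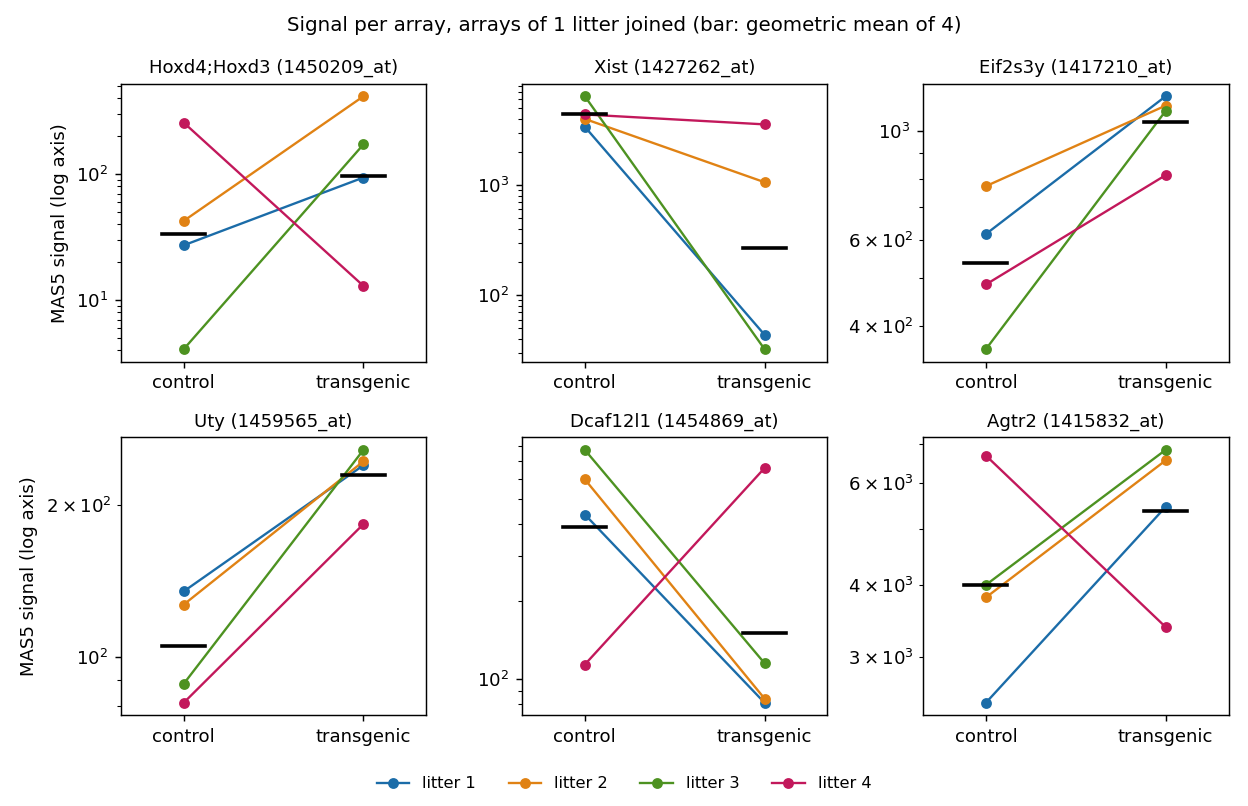
MAS5 signal on a log axis for 6 probe sets in the 8 arrays, with a line joining the control and the transgenic array of each litter and a bar at the geometric mean of the 4 arrays of a group. The Hoxd4 and Hoxd3, Dcaf12l1 and Agtr2 probe sets change one way in litters 1, 2 and 3 and the opposite way in litter 4, while Eif2s3y and Uty are higher in the array labelled transgenic in all 4 litters.

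For most tested probe sets, chondrocytes of both genotype labels had similar signals on these arrays. No probe set passed an adjusted p of 0.05 in limma, whose lowest adjusted p was 0.58, and 741 had an unadjusted p under 0.05 (358 higher and 383 lower in arrays labelled transgenic), against 1125.9 expected by chance. Of the tested probe sets, 22286 (98.97%) had a 95% interval that lay wholly within a 2-fold change and 19389 (86.1%) within a 1.5-fold change. These intervals hold for each probe set alone, for the groups as labelled, and on the scale with the constant added to the signal. That constant makes changes of dim probe sets smaller, so larger changes of their signals are not excluded. Probe sets too dim for the test are not covered. A difference beyond 2-fold was estimated for 10 probe sets. The control and transgenic arrays differed in the same direction in all 4 litters for 3028 probe sets (13.4%), where chance gives 12.5%. With the litter as a block, no probe set passed either (lowest adjusted p 0.26). In that fit 1242 had an unadjusted p under 0.05, more than the 1125.9 expected by chance. The lower count of 741 came from the fit that leaves differences between litters in its error. In simulated data of the same size the limma test recovered 91.1% of 2-fold and 60.1% of 1.5-fold changes among 22518 probe sets, and few smaller ones. These data had independent probe sets and no litter effect, so the rates in the real arrays may differ. Each simulated set also held 200 changed probe sets. With fewer changed ones the adjusted threshold is harder to pass, and the rates would be lower.

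Among the 24 genes with the largest differences that ran the same way in all 4 litters, Xist, the noncoding RNA made by the inactive X chromosome, had the largest, with a mean signal of 4543 ± 1312 (SD, n = 4) in controls and 1175 ± 1663 (SD, n = 4) in transgenics and a log2 fold change of -3.58 (95% interval -5.65 to -1.51). Uty and Kdm5d, Y-linked histone demethylase genes, and Eif2s3y, a Y-linked translation initiation factor, differed by 0.92, 0.75 and 0.92 on the log2 scale. The X-linked deubiquitinase gene Usp9x had the smallest p of any probe set, with an adjusted p of 0.58 in limma. Its log2 fold change was 0.68 (95% interval 0.44 to 0.91). The 6 other tested probe sets of Usp9x were also higher, but by less, 0.03 to 0.30. The named one is of the kind that can bind several transcripts. With all probe sets of that kind left out, the lowest adjusted p in limma was 0.9997. None of the 24 passed the adjusted threshold, and each is named only as one of the largest differences with an unadjusted p under 0.01.

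The other higher values belonged to autosomal genes of low to moderate signal. Dhx38, an RNA helicase of the spliceosome, had a log2 fold change of 1.04 (95% interval 0.49 to 1.58) and Cited2, a transcriptional coregulator, one of 0.59 (95% interval 0.24 to 0.94). Cnpy2, Trp53rka, Map2k3os, Rgs7bp, Ppp2r2a and Zfr lay between 0.60 and 0.87. Other tested probe sets of Cnpy2 and Ppp2r2a, and 1 of Zfr, went the opposite way, by -0.11 to -0.02. The 3 remaining ones of Zfr lay between 0.06 and 0.09, and a brighter probe set of Cited2 was at 0.15 (95% interval -0.10 to 0.41), higher in 2 of 4 litters.

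Lower values were found for Slc38a10, an amino acid transporter (-1.49, 95% interval -2.53 to -0.45), Smyd1, a muscle histone methyltransferase (-0.93), Nrarp, a feedback inhibitor of Notch signalling (-0.79), Birc3, an inhibitor of apoptosis (-0.71, 95% interval -1.01 to -0.41), and Cdh5, the cadherin of endothelial junctions (-0.60, 95% interval -0.94 to -0.27). Exd1, Zfp316, Pcyox1l, Aqp11, Nav2 and Fxyd2 lay between -0.73 and -0.59. The Slc38a10 value came from a dim probe set, and 4 of the 5 other tested probe sets of this gene lay between 0.01 and 0.16. Another probe set of Smyd1 had a log2 fold change of 0.37 another of Nrarp one of 0.08 and another of Nav2 one of -0.03.

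**Figure D2:**
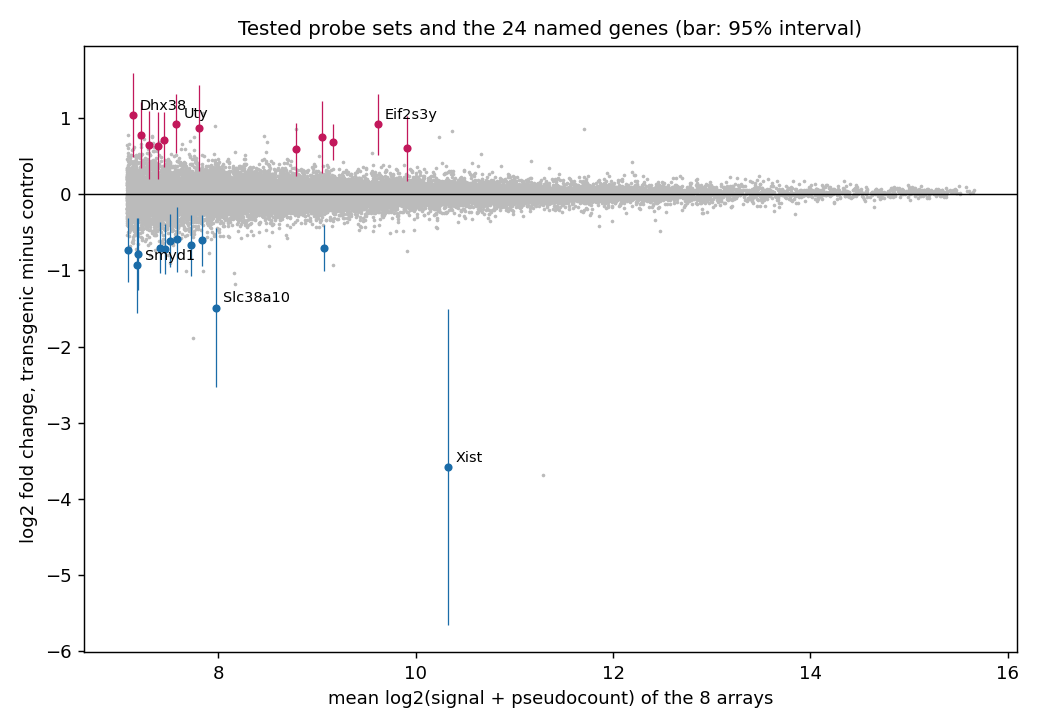
Log2 fold change, transgenic minus control, of the 22518 tested probe sets (grey points) against their mean log2(signal + 32) over the 8 arrays, with the 24 named genes in red (higher) or blue (lower) and their 95% intervals as bars. Xist, at -3.58, lies far below the other named genes, which range from -1.49 to 1.04.

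Y-linked genes were higher as a group. All 3 tested members (Eif2s3y, Uty and Kdm5d) were higher in the transgenic array of every litter, by a mean of 0.84. The exact permutation p was 0.029 over all assignments, which ignore the pairing, and 0.125 with labels exchanged only within litters, in each case the smallest possible. All 3 passed when adjusted over the list alone, against 0 over all probe sets tested. Eif2s3y had a mean signal of 558 ± 177 (SD, n = 4) in controls and 1054 ± 164 (SD, n = 4) in transgenics. The test of the list against other genes (camera) gave an adjusted p of 6.42e-09, and an adjusted p of 0.16 with an estimated correlation. The rotation test fry, which asks whether a list moves at all and not against other genes, gave an adjusted p of 0.50. The named Xist probe set had signals of 3386, 3992, 6412 and 4380 in the control arrays of litters 1, 2, 3 and 4 and of 43.6, 1062, 32.3 and 3561 in the transgenic arrays. The transgenic signals of litters 1 and 3 were near background, so the size of the change there depends on the added constant. Its brightest probe set was lower in litters 1, 2 and 3 but not in litter 4 (8098 in the control and 8209 in the transgenic array). Levels of Xist and of Y-linked genes, which differ between the sexes, thus moved with the genotype label beside every list described here. The labels do not give the sex of the embryos.

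No difference was found in the cartilage programme. Of the 25 tested genes of cartilage matrix, 17 were higher and 8 lower, all by less than 0.13 on the log2 scale, and none had an unadjusted p under 0.05 (camera adjusted p = 0.53). The smallest p values belonged to Col11a2 and Col11a1, chains of a minor cartilage collagen (0.07 and 0.06), Ucma, a secreted cartilage matrix protein (0.08), and Matn4, a matrilin (-0.07). No member's 95% interval reached beyond 0.48 to either side. Chondrogenic transcription factors gave 6 higher and 7 lower of 13 (adjusted p = 0.67), with Foxa3 at -0.22, Sox5 at -0.11 and Sox6 at -0.08. Of 13 hypertrophic chondrocyte genes 6 were higher and 7 lower (adjusted p = 0.70). Among them Alpl, the phosphatase of mineralising cells, had a mean signal of 932 ± 56.8 (SD, n = 4) in controls and 744 ± 60.7 (SD, n = 4) in transgenics (log2 fold change -0.31, 95% interval -0.51 to -0.12), lower in 4 of 4 litters, while Col10a1, the collagen of hypertrophic cartilage, was at 0.07. Alpl did not pass when adjusted over this list alone (0 of 13) but did over the list of osteoblast and bone genes (1 of 10). Glycosaminoglycan synthesis gave 22 higher and 13 lower of 35 (adjusted p = 0.51), with Chst12, a chondroitin sulphotransferase, at 0.22 and Has2, a hyaluronan synthase, at 0.17. Hedgehog and PTHrP signaling gave 6 higher and 8 lower of 14 (adjusted p = 0.96), with Gas1 at 0.21 and Gli3 at 0.10.

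Of the growth factor and patterning lists, BMP and TGF-beta signaling rose against other genes in camera at its preset correlation (adjusted p = 0.0080) but not with an estimated correlation (adjusted p = 0.16). In it 33 of 45 tested members were higher and 12 lower, by a median of 0.07, and 3 had an unadjusted p under 0.05: Bmp2, a bone morphogenetic protein (0.23, 95% interval 0.02 to 0.43), Id4, a helix-loop-helix inhibitor (0.19), and Bambi, a decoy receptor (0.15). None passed when adjusted over the list alone or over all probe sets (0 of 45). The call ended without control replicate 4 (adjusted p = 0.094), transgenic replicate 2 (0.15) or, in the fit with no block, both arrays of litter 2 (0.12; 0.035 and so kept with the block), and with the mean of all probe sets per gene (0.077). The adjusted p of fry was 0.99.

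No other signaling list was called. Wnt signaling gave 12 higher and 24 lower of 36 (adjusted p = 0.53), with Dkk3, a secreted Dickkopf family protein, at -0.37 and Axin2, a Wnt target, at 0.32. FGF signaling gave 11 higher of 15 (adjusted p = 0.53; Fgf7 0.21), Notch signaling 7 of 14 (adjusted p = 0.53; Notch3 -0.23, Notch1 -0.25) and the IGF axis 9 of 15 (adjusted p = 0.82; Htra1 0.10, Igf2 0.06). Cell cycle genes were split, 18 higher and 19 lower of 37 (adjusted p = 0.99; Melk -0.18, Mcm6 0.20). Cell cycle inhibitors and p53 targets gave 4 higher and 9 lower of 13 (adjusted p = 0.98; Ccng1 0.09, Bbc3 0.22). Of 15 tested Hox genes other than Hoxd4, 6 were higher and 9 lower (adjusted p = 0.96), with Hoxa7 at 0.26 (95% interval 0.01 to 0.52) and Hoxc5 at -0.28. Of 7 Hox cofactors 6 were higher (adjusted p = 0.53; Pbx3 0.05, Meis1 0.07). Matrix proteases and their inhibitors gave 10 higher and 10 lower (adjusted p = 0.82; Timp3 -0.24). Cell-matrix receptors 15 higher and 11 lower (adjusted p = 0.56; Dag1 0.12).

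Of the lists for other cell types, endothelium fell against other genes in camera at its preset correlation (adjusted p = 0.024) but not with an estimated correlation (adjusted p = 0.997). In it 12 of 18 tested members were lower and 6 higher, by a median of -0.22, and the list mean was lower in the transgenic array of 4 of 4 litters. Lists that were not called also had means that ran 1 way in all 4 litters: heat shock lower, glycosaminoglycan synthesis and interferon response higher. Cdh5 had a mean signal of 251 ± 47.3 (SD, n = 4) in controls and 153 ± 11.2 (SD, n = 4) in transgenics and passed when adjusted over the list alone (1 of 18), while Ecscr, Egfl7 and Kdr, other genes of blood vessel lining, were at -0.38, -0.30 and -0.23 and did not. The call ended without control replicate 2 (adjusted p = 0.26), control replicate 4 (0.19), transgenic replicate 1 (0.61) or, in the blocked fit, litter 1 (0.37) or litter 2 (0.16), and without both arrays of these litters in the fit with no block (0.25 and 0.20). It also ended with no filter (adjusted p = 0.25) and with the mean of all probe sets per gene (0.052), and the adjusted p of fry was 0.99. With the level of Xist as a covariate the mean of this list turned from -0.15 to 0.047 (camera adjusted p = 0.98). The mean was -0.028 without transgenic replicate 1 and ranged from -0.21 to 0.047 over all settings.

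Erythroid genes, markers of red blood cell precursors, gave 6 lower of 7 tested, by a median of -0.24, with Slc4a1 at -0.31, Alas2 at -0.28 and Hbb-b2 at -0.24. Their mean was lower in 4 of 4 litters, as was that of heat shock genes, a list not called. The erythroid list passed camera with the litter as a block (adjusted p = 1.57e-04) but not without it (adjusted p = 0.36). With an estimated correlation, run without the block alone, the adjusted p of camera was 0.997. With the block, fry gave an adjusted p of 0.17. Skeletal muscle genes gave 20 higher of 26 (adjusted p = 0.25; Myf5 0.43, Ckm 0.37) and were called in 7 of 30 alternatives, among them without transgenic replicate 1 (adjusted p = 2.5e-07). Of the other lists, fibroblast and perichondrium genes gave 16 higher of 25 (adjusted p = 0.67; Twist1 -0.23, Fn1 0.07), and tendon and joint genes 6 of 10 (adjusted p = 0.90; Sfrp5 -0.31, Gdf5 0.25). Osteoblast and bone genes gave 4 higher and 6 lower (adjusted p = 0.52; Smpd3 -0.10, Omd 0.17), osteoclast genes 4 and 4 (adjusted p = 0.83; Acp5 -0.19), and smooth muscle and pericyte genes 7 and 4 (adjusted p = 0.98; Cspg4 0.09). Macrophage genes gave 5 higher and 6 lower (adjusted p = 0.83; Cd14 0.18, C1qb 0.36), granulocyte precursor genes 3 and 2 (adjusted p = 0.98; S100a9 -0.19), adipocyte genes 1 and 5 (adjusted p = 0.53; Fabp4 -0.24), nerve and Schwann cell genes 5 and 2 (adjusted p = 0.70; S100b -0.08) and epidermis genes 1 and 3 (adjusted p = 0.82; Lor -0.21). Only 2 lymphocyte genes (Ebf1 -0.12, Cd8a 0.03) and 1 mesothelium gene (Krt8 -0.30) were bright enough, which was too few for a list test.

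Of the stress lists, immediate early genes, which tissue dissociation can induce, rose against other genes in camera at its preset correlation (adjusted p = 0.0024) but not with an estimated correlation (adjusted p = 0.997). In it 22 of 26 tested members were higher, by a median of 0.06, with Klf4 at 0.29 (95% interval 0.05 to 0.53), Nr4a2 at 0.29 and Dusp1 at 0.17 as the 3 members with an unadjusted p under 0.05; 0 passed when adjusted over the list alone. The call ended without control replicate 4 (adjusted p = 0.19), transgenic replicate 2 (0.58), transgenic replicate 3 (0.18) or, with or without the block, litter 3 (0.31 and 0.36). The adjusted p of fry was 0.99. With the level of Xist as a covariate the list mean went from 0.088 to 0.0079 and the direction of the test turned (camera adjusted p = 0.99). The mean was 0.025 without transgenic replicate 2 and ranged from 0.0079 to 0.16 over all settings. Heat shock genes gave 5 higher and 10 lower of 15 (adjusted p = 0.67; Hspa1b -0.11), genes of endoplasmic reticulum stress 10 and 12 (adjusted p = 0.98; Pdia4 -0.20), hypoxia and glycolysis 14 and 13 (adjusted p = 0.97; Hif1a 0.09) and the interferon response 5 and 2 (adjusted p = 0.53; Oas1a 0.77, 95% interval -0.03 to 1.58). Housekeeping genes gave 8 higher and 3 lower (adjusted p = 0.48; Hprt 0.14, Actb 0.06). The ratio of 3' to 5' signal, a sign of RNA quality, was 0.732 ± 0.009 and 0.734 ± 0.033 (SD, n = 4) for Gapdh (exact permutation p = 0.94) and 1.62 ± 0.054 and 1.66 ± 0.070 (SD, n = 4) for Actb (exact permutation p = 0.40).

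For 6 lists the signs of the median, the mean and the test were not all alike: cell cycle inhibitors and p53 targets, smooth muscle and pericyte, endoplasmic reticulum stress, macrophage, granulocyte precursor, and hypoxia and glycolysis, each with a mean between -0.013 and 0.048. The lists not named as passing had 0 members past the threshold when adjusted over the list alone, except osteoblast and bone.

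**Figure D3:**
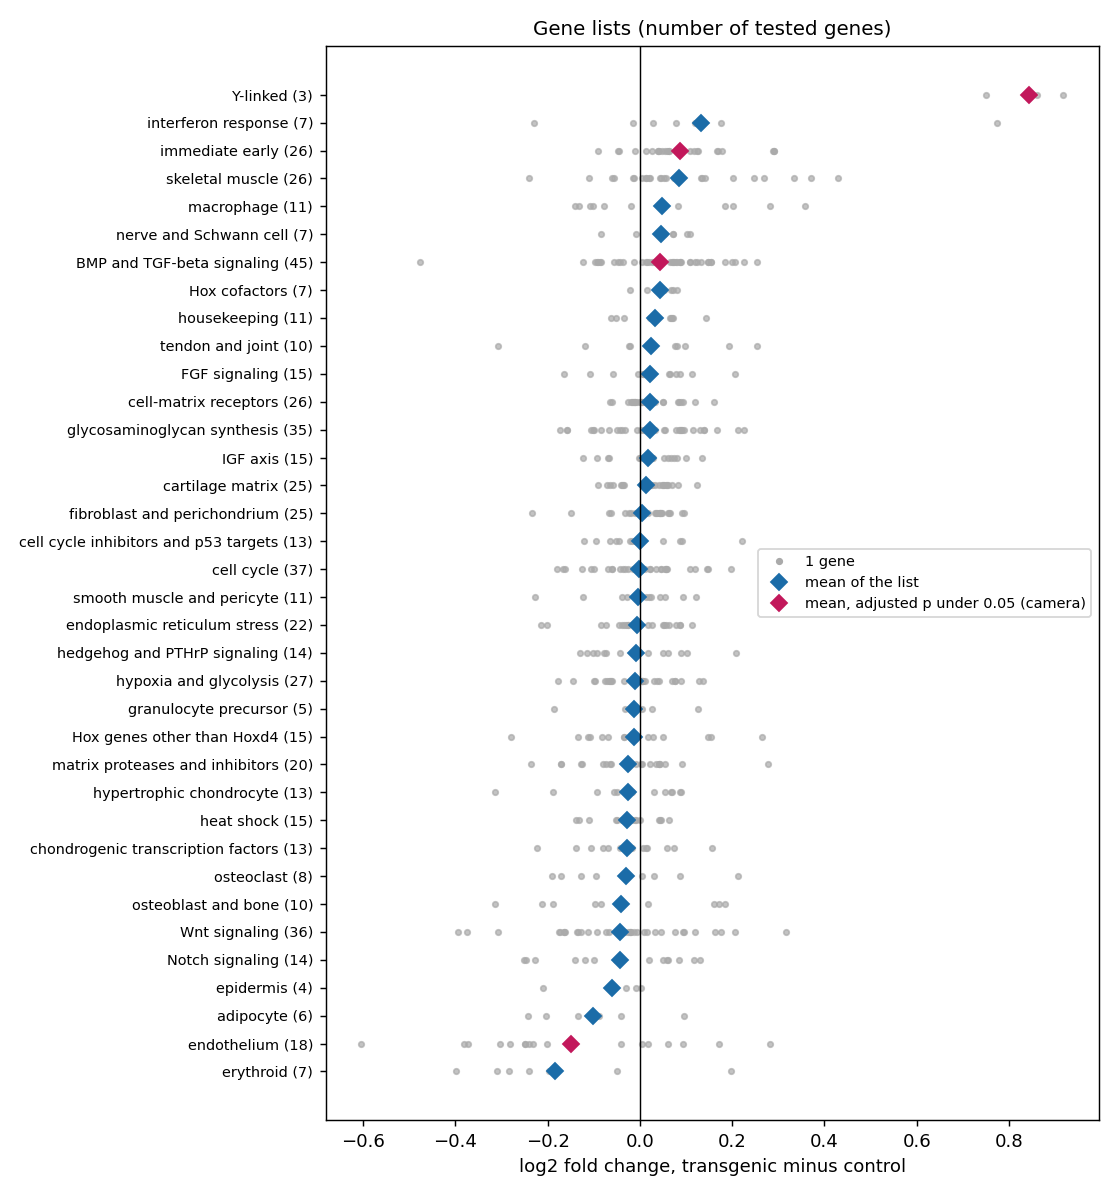
Log2 fold change, transgenic minus control, for the 36 gene lists with at least 3 tested genes, where each grey point is 1 gene and each diamond the mean of a list; red diamonds mark the 4 lists with a camera adjusted p under 0.05. Apart from the Y-linked list at 0.84, every list mean lies between -0.18 and 0.13.

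Without litter 4, whose arrays went against the others for the Hoxd4 and Hoxd3 probe set, a few probe sets passed the test in the remaining 6 arrays. In the fit with the litter as a block 4 passed: both probe sets of Dcaf12l1, a gene of the WD-repeat family (log2 fold changes -2.32 and -2.08, limma adjusted p = 5.93e-04 for each), Agtr2, the type 2 angiotensin receptor (0.89, adjusted p = 0.0023), and an Xist probe set (-2.47, adjusted p = 0.014). Without the block the Dcaf12l1 pair alone passed (adjusted p = 0.0031). In litter 4 the same Dcaf12l1 probe sets differed by 2.25 and 2.09 and Agtr2 by -0.98, the opposite direction. Over all 8 arrays the log2 fold changes were -1.18 and -1.04 for Dcaf12l1 and 0.42 for Agtr2, none past the threshold. These genes were chosen after their values were seen.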

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

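In this part, the tests of an exchange of labels by splits of the arrays, of probe set noise, of sex makeup as a cause of the litter 4 pattern, of overall signal, of an effect on Xist alone, of the estimated correlation as a cause (from a fit planned before) and of the splits for probe sets were chosen only after their results were seen; the share of probe sets that turned in litter 4, the escape genes and the splits for gene lists were tested after their bounds were written. A single array stood far from the other 3 of its group in 25 of the 414 groups of 4 values looked at, where chance gives about 20.7.

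Both arrays of litter 4 were among these: its control array had a signal of 256 for the brighter probe set shared by Hoxd4 and Hoxd3, where the other controls lay between 4.10 and 42.6, and its transgenic array had signals of 659 and 571 for the Dcaf12l1 probe sets, where the other transgenic arrays lay between 80.7 and 143. A sex makeup opposite to that of the other litters is argued against by the named Xist probe set, which differed by -0.30 on the log2 scale in litter 4, and noise of a dim probe set by Agtr2, whose signal was 2505 or more on every array, and by both Dcaf12l1 probe sets, which changed together in each litter. For Hoxd4 itself such noise stays open, since an SD at percentile 100 of the 1000 probe sets nearest in mean only restates the pattern. An exchange of labels between the 2 arrays of litter 4 stays a hypothesis: the split that exchanges them gave 4 probe sets with an adjusted p under 0.05, against 0 as labelled and 0 for each other of the 8 splits that part every litter (3 against 1 at most with the block), too few splits for a share under 0.05. The exchange was raised because probe sets turned in litter 4, so the 4 probe sets of this split may only restate that pattern. The test was first set over all 35 splits, where a split that parts no litter gave 5 and so argued against the exchange. It was limited to the 8 only after both values were seen. Of the probe sets with an unadjusted p under 0.01 in the other 3 litters, 42.1% went the opposite way in litter 4 (95% interval 34.8 to 49.6). With litter 1, 2 or 3 left out instead, the share was 43.1%, 40% and 54.4%, so litter 4 did not stand apart from the others by this measure. The 42.1% lay between the bounds written before, so an exchange with effects across many genes was neither shown nor excluded. The interval takes probe sets as independent, though all were read on the same 2 arrays of litter 4, and so is likely too narrow.

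The Y-linked list also had an array apart, control replicate 3, with a mean log2 value of 8.10 where the other controls lay between 8.90 and 8.98. More male embryos in the pools labelled transgenic stay a candidate explanation of higher Y-linked genes and lower Xist. Kdm6a, Eif2s3x, Ddx3x and Kdm5c, X-linked genes that escape inactivation and would be lower in male pools, had a mean log2 fold change of -0.12 (95% interval -0.34 to 0.10), a mean not beyond the spread between arrays; of the 4, Eif2s3x alone had an interval wholly below 0 (-0.16, 95% interval -0.32 to -0.003). A difference in overall signal, which moves genes 1 way, is argued against by Xist at -3.58 (95% interval -5.65 to -1.51) beside the mean of the Y-linked genes at 0.84 (95% interval 0.23 to 1.46), and an effect of the transgene on Xist alone by the latter. These tests replaced, after all values were seen, the median log2 fold change of all tested probe sets (0.0029), which the scaling of the arrays holds near 0, and a test of an effect on Xist in every pool, which had used the -0.30 of litter 4.

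The 4 called gene lists may reflect genes of a list that vary together between pools rather than the genotype label, since 0 lists passed with the correlation estimated from the data. Of the 35 splits of the 8 arrays 22 gave at least 4 lists, with 14 the highest of the others, so chance cannot be excluded. Of the 8 that part every litter, free of the litter differences in the others, 2 gave at least 4, with 5 the highest of the others, too few splits for a share under 0.05. Likewise 27 of the 35 splits gave at least the 741 probe sets with an unadjusted p under 0.05, and the highest gave 2476. Of the 8 that part every litter 3 did, with 987 the highest of the others. The split with 2476 sets whole litters against each other, which points to a structure of the arrays by litter. The 0 past the adjusted threshold could not be tested this way, since all 35 splits have at least 0 (5 at most). Of the 8 splits that part every litter, the labelled one had 1242 in the blocked fit and the highest of the others 1784.

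Other arrays stood apart for single genes. Among transgenic arrays, replicate 4 was highest for Alpl (835) and Ngp (626) and lowest for Ebf1 (922) and Id4 (2555), replicate 3 was highest for Pcyox1l (121), replicate 2 for Dusp1 (18546), and replicate 1 for Cspg4 (4526), Pdia6 (6912) and Perp (232). Among control arrays, replicate 1 was highest for Aqp11 (335) and Pth1r (4517) and lowest for Wnt5b (131), replicate 2 was highest for Htra1 (3720) and Melk (999), replicate 3 was highest for Aurkb (651) and lowest for Fabp7 (281), and replicate 4 was lowest for Bmp2 (1428). For list means on the log2 scale, transgenic replicate 2 was highest for hedgehog and PTHrP signaling (10.51), and transgenic replicate 1 was lowest for Notch signaling (8.63), fibroblast and perichondrium (12.85) and interferon response (8.38).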

How the results depend on the processing

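Among the alternatives, leaving out both arrays of a litter without the block and the Xist covariate were added after seeing the data. No probe set passed in limma under any alternative that kept all 8 arrays, the replicate block included (0, lowest adjusted p 0.26); the lowest adjusted p of these was 0.061, with the Xist covariate. At an adjusted p under 0.1, 0 passed in the fit without block or covariate, where alone this was counted. Leaving out 1 array or, with the block, 1 litter gave 0 to 4 probe sets: 4 without litter 4, 1 (an Xist probe set, adjusted p 0.0295) without transgenic replicate 4 and 0 otherwise; without the block, leaving out litter 4 gave 2. These fits rest on fewer arrays, and the cause was not tested further than in the flagged results. The log2 fold change of the brighter Hoxd4 probe set, 0.87, ranged from 0.30 to 2.06 without 1 array or litter, and was 1.47 with a pseudocount of 1, 0.48 with 4 times the pseudocount and 0.27 with the Xist covariate. The constant added to the signal sets the size of a change in a dim probe set. That of the dimmer one, -0.12, ranged from -0.27 to 0.049, with its sign turned without control replicate 4 (0.049) and without litter 4 (0.013).

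The 4 called gene lists became 5 with the replicate block (erythroid joined them), 2 with the filter at the 75th percentile, 2 with the mean of all probe sets per gene, 0 with an estimated correlation and 0 with fry, which tests against no change rather than against other genes. Without 1 array they ranged from 1 (control replicate 4) to 6, with 2 without transgenic replicate 2. Without 1 litter they ranged from 4 to 8 with the block, the 8 without litter 2, and from 3 to 4 with no block, where leaving out litter 2 gave 3. The Y-linked list was called in 27 of 29 alternatives, BMP and TGF-beta signaling in 24 of 30, immediate early in 22 of 30 and endothelium in 17 of 29. Of lists not called, skeletal muscle passed in 7 of 30 (adjusted p down to 2.5e-07, mean between 0.0015 and 0.28), erythroid in 7 of 30, granulocyte precursor in 4 of 29, fibroblast and perichondrium in 4 of 30, and epidermis, macrophage, and hypoxia and glycolysis in 1 each. With Xist as a covariate, 6 lists were called, and the mean log2 fold change turned from -0.15 to 0.047 for endothelium, from 0.088 to 0.0079 with a turned test for immediate early, and from -0.013 to 0.49 for granulocyte precursor; the last ranged from -0.30 to 0.29 without 1 array or litter. The cause of these changes was not tested. The replicate block changed no other call.

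Of 649 values of the 24 named genes under the alternatives, 1 changed sign and 0 passed the adjusted threshold (lowest adjusted p 0.061). These genes were chosen for a difference in the same direction in every litter and a low unadjusted p. Leaving out a litter therefore could not turn their sign, and a turn was unlikely in other fits of the same arrays. Their stable signs follow from this choice and do not show robustness to the processing. Probe sets with a mean below the median, the Hoxd4 pair among them, were left out of the test, and MAS5 signals are noisy near background, which limits what can be said of dim genes.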

Other observations

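The genes of the litter comparison were chosen after their values were seen; the test of the pairings of control with transgenic arrays and that of Hba-x had their bounds written first.

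In a fit with both terms, 109 probe sets differed between the 4 litters at an adjusted p under 0.05 in limma, where the genotype label gave 0. Of the 24 ways to pair the control with the transgenic arrays, the labelled litters alone gave as many (1 of 24), so chance is excluded only at the smallest share that 24 pairings can give. The highest of the others gave 87 and keeps litters 1 and 4 while it exchanges 2 and 3, so these values do not settle how the arrays of litters 2 and 3 pair. A gene was counted if any of its tested probe sets differed between litters, so genes with more probe sets had more chances. The 87 such genes held more members of 6 fixed lists than the 11016 tested genes would give. The hypergeometric test used takes genes as independent, which they are not. By this test the lists were tendon and joint (4 of 10, adjusted p = 2.79e-05), erythroid (3 of 7, adjusted p = 3.09e-04), fibroblast and perichondrium (4 of 25, adjusted p = 5.12e-04), macrophage (3 of 11, adjusted p = 7.13e-04), endoplasmic reticulum stress (3 of 22, adjusted p = 0.0050) and the IGF axis (2 of 15, adjusted p = 0.038). Cartilage matrix had 0 of 25.

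Genes of the litter comparison went both ways in litter 1. Tnmd, a tendon glycoprotein, had a mean signal of 7781 in its 2 arrays against 9544 to 12006 in the other litters, Lox, a collagen crosslinking enzyme, 3548 against 4791 to 6030, Col14a1 8415 against 10269 to 12362, and Mrc1, a macrophage receptor, 88.4 against 178 to 484. Litter 1 had the highest signal of Serpinh1, a collagen chaperone, and Omd, a bone matrix protein, 25173 and 13682, against 16419 to 23256 and 9531 to 13235, and of Chac1 and Me1, 1980 and 2390, against 789 to 1284 and 1080 to 1585. Mt1 and Mt2, metallothioneins, were lowest in litter 4, at 8092 and 5543, against 11995 to 14842 and 7669 to 9880.

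Litter 3 had the highest signal of Hbb-y, an embryonic beta-like globin, at 1977 against 495 to 595 in the other litters (3.44-fold). A candidate explanation is an earlier stage of red blood cell development in that litter. Hba-x, an embryonic alpha-like globin, was 2.23-fold higher in litter 3 and above every other array in both of its arrays, as this explanation needs. Alas2 and Hbb-b2, which red cell precursors of later stages also express, were 1.66-fold and 1.58-fold higher, so more red cells with embryonic globin among them stay open too; the labels give no stage finer than E18.5.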
